A study of Gallus gallus with 9 samples.

How the data were processed

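Olfactory placodes, ectodermal thickenings of the head from which the olfactory epithelium and the neurons producing gonadotropin-releasing hormone (GnRH) arise, were taken from chick embryos at Hamburger and Hamilton (HH) stages 16, 18 and 20. Each stage had 3 samples, which the labels call biological replicates. The labels do not say how many embryos were pooled in a sample or on which days samples were taken. Per the labels' protocols, total RNA was extracted with Trizol, then amplified and labelled with biotin using kits from NuGEN. Each sample was hybridised to 1 array.

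The deposited table gives 1 intensity per probe set and array on a linear scale, and MAS5 is the tool that the submitters' processing notes name, with its version and scaling not given in the sources used here. MAS5 combines the probe pairs of a probe set into 1 signal, and it may scale each array to a common target. A common target was absent from the deposited values: the mean signal of an array, after trimming 2% at each end, ranged from 68.75 to 162.8. The highest mean, that of HH16 replicate 1, was 2.37 times the lowest. Detection calls and scanner files were not used here.

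The table held 38535 probe sets. Of these, 37693 were chicken probe sets, 689 were probe sets for viruses, 96 were controls and 57 were reporter genes, and the latter 3 kinds were left out of all tests. The platform annotation gave 27166 chicken probe sets exactly 1 gene symbol, 177 several symbols and 10350 none. Symbols were compared, through Entrez gene numbers, with the RefSeq gene table of the assembly GRCg7b, and 0 symbols had to be updated. A probe set with several symbols or none names no gene here. No coordinates are given, because the table pairs probe sets with no genome build.

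Values were transformed as log2(intensity + 16) and quantile normalized between the 9 arrays, so a fold change is on the scale of normalized log2(intensity + 16) and understates the change of dim genes. Before the data were examined, it had been fixed that the deposited values would be tested with no further normalization, on the assumption that MAS5 had scaled them. Quantile normalization replaced this before any test was run, when the arrays proved not to be scaled, and the unnormalized values became an alternative. A chicken probe set was tested if it lay above the 40th percentile of its array on at least 3 of the 9 arrays, which left 24489 probe sets, 18873 of them with 1 symbol, for 10616 of the 13008 genes on the array. Where a gene had several probe sets, the one with the highest mean over all arrays represented it. Among 197 calls of named genes, 106 had other tested probe sets, of which 41 had another probe set called in the same direction, 64 had none called, and 1, RPL10A, had one called in the opposite direction.

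All 9 arrays entered 1 linear model with a mean for each stage, fitted with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3. The fit had 6 residual and 11.1 prior degrees of freedom. Each of the 3 differences between stages was tested two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A moderated F test asked which probe sets changed at all, and a further contrast asked whether the later step (HH18 to HH20) differed from the earlier step (HH16 to HH18). An error given with a log2 change is the standard error of that fit, and one given with a stage's level is the SD over its 3 arrays. The p-values measure the spread between these samples. The number of arrays limits the precision, and the median standard error of a stage difference was 0.148 on the log2 scale.

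Gene lists were tested with limma's camera at its preset correlation of 0.01 over the representative probe sets, with adjustment over the 23 lists. The lists were GnRH neuron and Kallmann-related genes, placodal transcription factors, Notch and proneural genes, neuronal differentiation, the olfactory receptor neuron lineage, axon guidance and adhesion, the FGF, retinoic acid, BMP and WNT pathways, cell cycle, surface and nasal epithelium, neural crest and ensheathing glia, mesenchyme, blood vessel, erythrocyte, macrophage and leukocyte, lens, eye and forebrain, immediate early and stress genes, hypoxia and glycolysis, apoptosis, and ribosomal proteins. A gene could be in several lists. Camera with an estimated correlation and fry were run as alternatives. Of the 11 list calls, 1 held with an estimated correlation, that of the BMP pathway from HH18 to HH20.

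The gene lists, the tests, the filter, the pseudocount and the rule for named genes were fixed before the data were examined. The rule named the 12 largest rises and falls from HH16 to HH20, and the 8 largest of each in either step, among called genes whose 3 arrays of 1 stage all lay above the 3 of the other. It also named up to 4 called members of each list with the largest change, and 15 genes of GnRH neurons, neurogenesis and the placode whether called or not. Of those 15, 2 are not reported here. In addition, PCP4, DLL1, HES5 and IL17RD are named for HH20 against HH16 as members of their lists that fell, a choice made after their values were seen. SRI and RBM10 are named because the steps of a probe set of each differed, likewise after their values were seen. In both genes it was not the probe set that represents the gene. Under each alternative a gene kept the probe set that represented it here, which was decided after a run of the alternatives in which it was picked anew.

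A probe set that did not exceed, on any array of a stage, the 99th percentile of that array's virus probe sets was taken as not well above background there. Its change is given as a bound, set from the mean of the bright stage against the higher of that percentile and the dim probe set's own value on each array. This measure of background was chosen after the data were seen. The calculation was tested on simulated data built from the real means and spreads of HH20 against HH16, with 200 of 24489 probe sets changed in each of 5 simulations: 36.7% of 1.5-fold changes, 81.5% of 2-fold changes and 97% of 3-fold changes were called, 5.8% of calls were false, and an unchanged comparison gave 0 calls by limma. Camera found 20 of 20 shifted lists of 40 genes and 0 of the unshifted lists, counted at an unadjusted p under 0.05. The noise of each simulated probe set was drawn independently, whereas the neuronal and the Notch and proneural lists had estimated correlations of 0.073 and 0.17. These simulated lists therefore cannot show how camera behaves for correlated genes.

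The alternatives were no normalization between arrays, centring on medians, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, a variance prior without trend, array weights, the replicate number as a block, removal of probe sets designed against several transcripts, a fit to the 6 arrays compared, the mean over a gene's probe sets, and leaving out each array in turn. Scaling to a trimmed mean, a filter at the virus percentile and a fit without HH16 replicate 1 and HH18 replicate 2 were added after the data were seen.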

Results

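Gene expression in the chick olfactory placode was measured at HH16, HH18 and HH20, stages that the title of the series places at the start of GnRH neuron production. Each stage was represented by 3 samples, and the 9 samples were each read on 1 Affymetrix chicken array. The signal summed over an array ranged from 3670608 in HH18 replicate 1 to 8339401 in HH16 replicate 1. The share of probe sets brighter than the 99th percentile of the array's virus probe sets ranged from 46.9% in HH18 replicate 2 to 59.6% in HH16 replicate 1. The number of arrays, 3 per stage, limits the precision of the values. The p-values given are limma's, adjusted over all tested probe sets unless a list is named, and they measure the spread between these samples.

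The arrays separated by stage. The leading principal component, which held 33.8% of the variance, placed the HH16 arrays between -27.92 and -24.49, the HH18 arrays between 3.07 and 10.45 and the HH20 arrays between 18.62 and 20.68. The next component held 14.7% of the variance and spread the HH18 arrays from -29.45 in replicate 2 to 15.36 in replicate 3. Pearson correlations across tested probe sets, which are not independent replicates, were 0.984 to 0.993 between arrays of the same stage and 0.979 to 0.989 between arrays of different stages, and no pair of arrays held identical values. HH18 replicate 2 also had the brightest virus probe sets, with a 99th percentile of 13.9 against 6.17 to 8.70 on the other arrays.

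**Figure D1:**
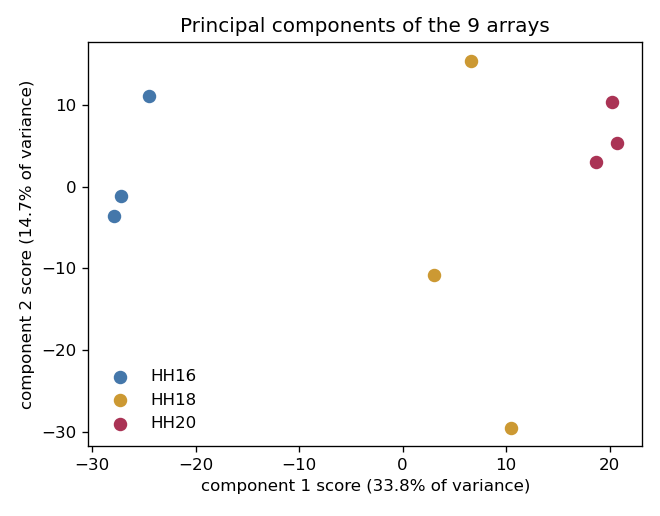
Scores of the 9 arrays on principal component 1 (x axis) and principal component 2 (y axis) of the quantile-normalized log2 values, with 1 point per array coloured by stage. Component 1 held 33.8% of the variance and ordered the stages without overlap, and HH18 replicate 2 lay at -29.45 on component 2.

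The comparison of HH20 with HH16 asks what changed in the placode over the whole period. Of the 39 tested members of the list of neuronal differentiation genes, 21 rose, 1 fell and 17 did not pass (23 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.45. The list shifted upward against other genes (camera adjusted p = 1e-09, adjusted p = 0.17 with an estimated correlation). Chromogranin A (CHGA), a protein of secretory granules, rose 2.96-fold (log2 change 1.57 ± 0.15, SE, n = 3 per stage, adjusted p = 4.6e-06). STMN2, a regulator of microtubules in growing axons, rose 2.43-fold (1.28 ± 0.12, adjusted p = 2.9e-06). ELAVL2, an RNA-binding protein of neurons, rose 2.28-fold (1.19 ± 0.14, adjusted p = 2.2e-05), and SCG3, another granule protein, rose 2.06-fold (1.04 ± 0.17, adjusted p = 0.00065). The member that fell was PCP4, a calmodulin-binding peptide of neurons, at a log2 change of -1.0 ± 0.15 (adjusted p = 0.00037).

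In the Notch and proneural list, 9 of 24 tested members rose, 2 fell and 13 did not pass (11 rose and 3 fell adjusted over the list alone), with camera adjusted p = 0.0081 and adjusted p = 0.37 with an estimated correlation. NEUROG1, a proneural factor, rose 2.15-fold (log2 change 1.10 ± 0.15, adjusted p = 0.00013) and NHLH2, a helix-loop-helix factor of newly formed neurons, rose 2.92-fold (1.54 ± 0.17, adjusted p = 1.3e-05). Of the Notch ligands, JAG1 rose by a log2 change of 1.05 ± 0.16 (adjusted p = 0.00044), while DLL1 changed by -0.82 ± 0.13 (adjusted p = 0.00066). HES5, a transcriptional target of Notch, changed by -0.59 ± 0.11 (adjusted p = 0.0025). In the list of the olfactory receptor neuron lineage, 5 of 13 tested members rose, 1 fell and 7 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.085, fry adjusted p = 0.018). The members that rose included the transcription factors LHX2 (1.29 ± 0.15, adjusted p = 2.2e-05), EBF2 (0.78 ± 0.14, adjusted p = 0.0017), EBF3 (0.63 ± 0.12, adjusted p = 0.002) and EMX2 (0.69 ± 0.16, adjusted p = 0.0082).

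**Figure D2:**
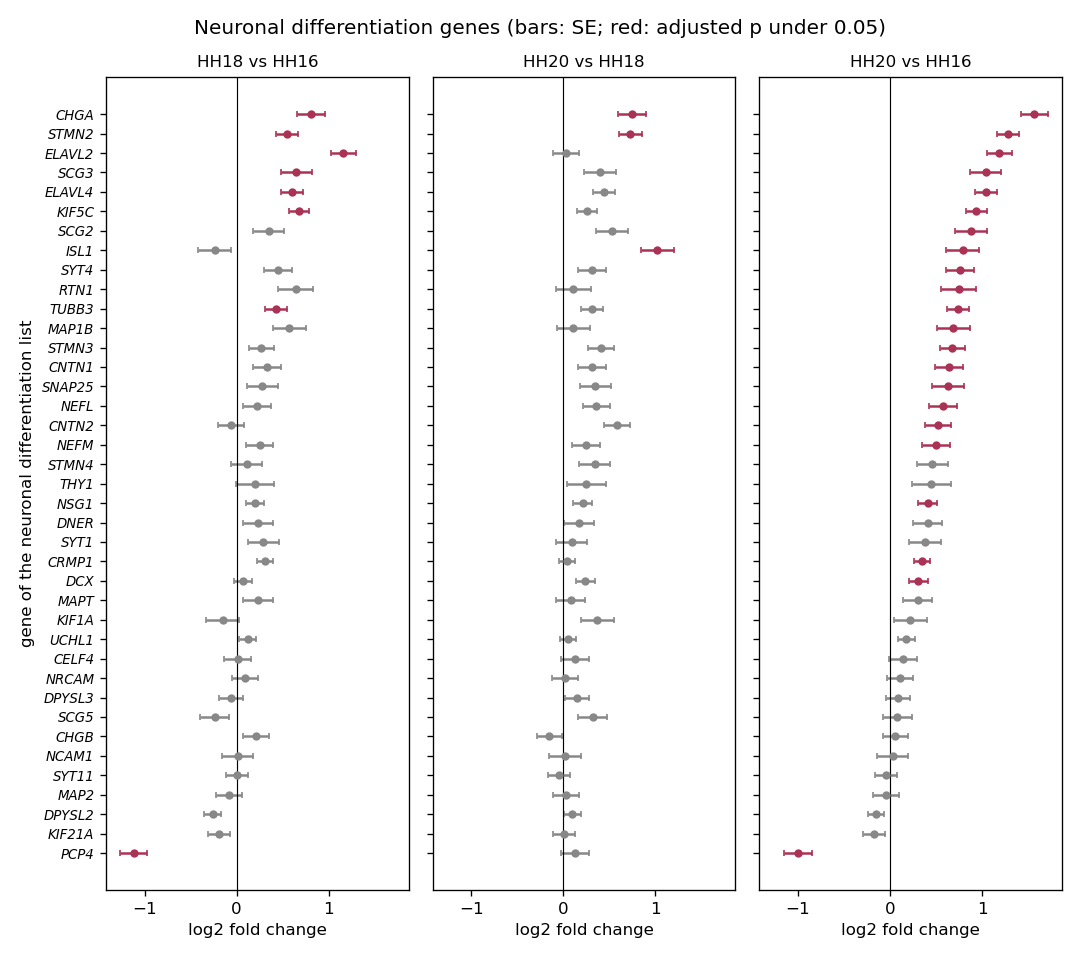
Log2 fold change (x axis) of the 39 tested genes of the neuronal differentiation list (y axis, ordered by their change from HH16 to HH20) in the 3 comparisons of stages, 1 per panel. Points are fitted changes with their SE and red marks an adjusted p under 0.05, which 21 genes that rose reached from HH16 to HH20, 3 from HH18 to HH20 and 7 from HH16 to HH18. From HH16 to HH18 the list's median was 0.22, and -0.04 as deposited, where the median of all tested probe sets was -0.25.

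Among the 12 rises named by the fixed rule, the largest was that of SST1, which encodes a somatostatin precursor and rose 7.93-fold, from a log2 level of 5.14 ± 0.29 (SD, n = 3) to 8.13 ± 0.27 (adjusted p = 5.7e-07). The zinc finger transcription factor GATA3 rose 3.63-fold (1.86 ± 0.17, adjusted p = 2.9e-06) and TMEFF2, a membrane protein with follistatin-like domains, rose 3.70-fold (1.89 ± 0.12, adjusted p = 1.3e-07). The other named rises were those of the glutathione transferase GSTA4 (3.84-fold), the membrane protein STOM (3.54-fold), the dopamine receptor DRD5 (3.53-fold), the lipid-binding FABP6 (3.50-fold), the calcium-binding S100A1 (3.46-fold), the engulfment receptor MEGF10 (3.17-fold), the cation channel TRPC4 (3.10-fold) and the growth factor FGF3 (3.05-fold). The phospholipase gene PLA2G10L was not well above background at HH16 and was at least 2.81-fold higher at HH20 (adjusted p = 2.2e-05). TNFSF13B, a cytokine of the tumour necrosis factor family, was 5.45-fold lower at HH20 (log2 change -2.45 ± 0.14, adjusted p = 5.9e-08). SNTN, a protein of the tips of motile cilia, was 5.10-fold lower, the lectin-domain gene CLEC19A 4.57-fold, HAPLN1, which links hyaluronan to proteoglycans, 4.23-fold, IGSF21 4.21-fold, the neuropeptide galanin (GAL) 4.20-fold and SH3BGR 4.10-fold. Also lower were the kinase CAMK1G (3.17-fold), PRTG, an immunoglobulin-domain receptor of early embryos (2.95-fold), the orphan nuclear receptor NR6A1 (2.91-fold), the steroid reductase AKR1D1 (2.88-fold) and the muscle LIM protein CSRP3 (2.77-fold). MEGF10 was well above background on 2 of the 3 HH16 arrays and CSRP3 on 1 of the 3 HH20 arrays. All 24 of these changes kept their direction and remained past the threshold with each of the 6 arrays left out.

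**Figure D3:**
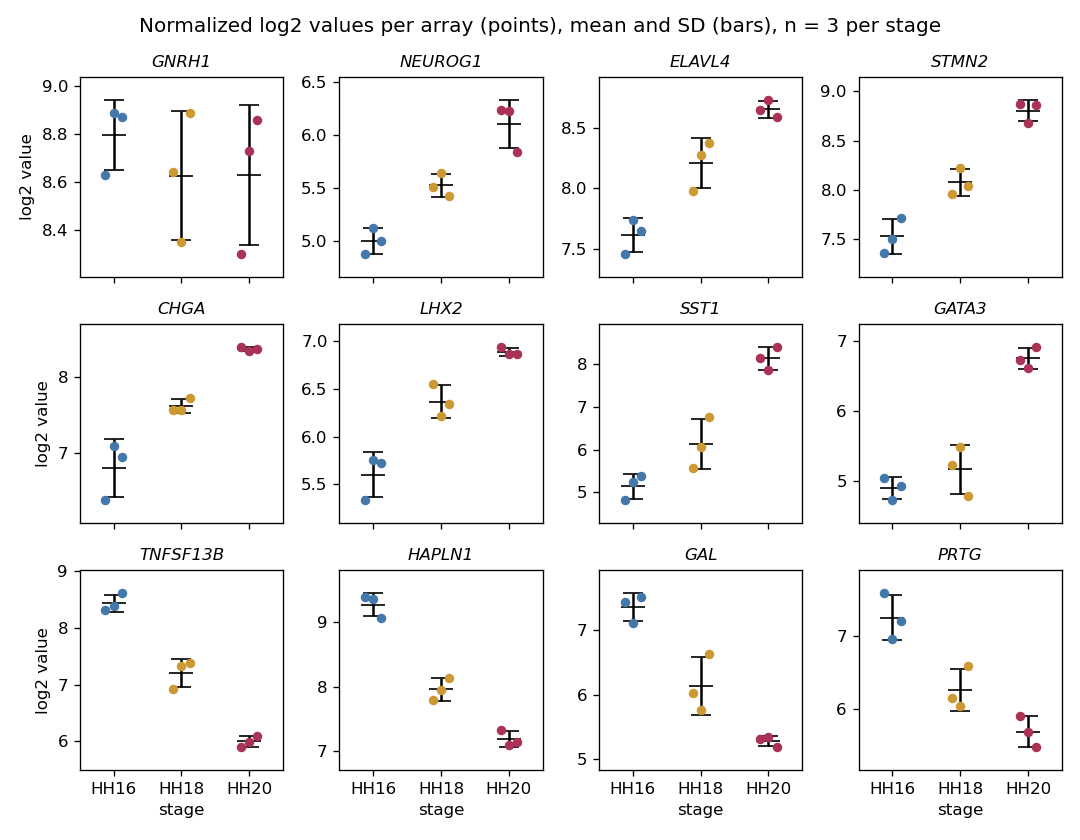
Normalized log2 values (y axis, with a range that differs between panels and does not start at 0) at each stage (x axis) for 12 genes. Points are single arrays and black marks the mean and SD of the 3 arrays of a stage: the mean of SST1 went from 5.14 at HH16 to 8.13 at HH20, that of TNFSF13B from 8.44 to 6.0 and that of GNRH1 from 8.80 to 8.63.

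In the retinoic acid list 6 of 16 tested members rose, 1 fell and 9 did not pass (7 and 2 adjusted over the list alone, camera adjusted p = 0.075). ALDH1A3, which makes retinoic acid, rose (log2 change 0.87 ± 0.09, adjusted p = 6e-06), and so did CYP26A1, which degrades it (0.99 ± 0.14, adjusted p = 0.00025), and DHRS3, which returns its precursor to retinol (0.75 ± 0.11, adjusted p = 0.00031). In the FGF list 5 of 22 rose, 2 fell and 15 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.081). The growth factors FGF3, FGF18 (1.07 ± 0.15) and FGF19 (0.89 ± 0.15) rose together with FGFRL1, a receptor without a kinase domain (0.86 ± 0.12), while IL17RD, an inhibitor of FGF signalling, changed by -0.74 ± 0.13. In the BMP list 4 of 26 rose, 1 fell and 21 did not pass (4 and 2 adjusted over the list alone, camera adjusted p = 0.085). Its rises included BAMBI, a pseudoreceptor that dampens BMP signalling (0.96 ± 0.13), and the BMP targets ID2 (0.67 ± 0.07) and ID4 (0.64 ± 0.11). In the WNT list 3 of 31 rose, 3 fell and 25 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.3). The ligand WNT4 rose (0.74 ± 0.16), and the ligand WNT2B (-1.30 ± 0.12) and the receptor FZD7 (-0.80 ± 0.15) fell. The FGF list passed without HH16 replicate 2 (adjusted p = 0.046) or HH20 replicate 1 (adjusted p = 0.048), with arrays centred on their medians (adjusted p = 0.024), as deposited (adjusted p = 0.044) and without probe sets designed against several transcripts (adjusted p = 0.025). The retinoic acid list passed without HH16 replicate 2 (adjusted p = 0.034), with arrays centred on their medians (adjusted p = 0.037) and with the mean of a gene's probe sets (adjusted p = 0.017). The BMP list passed with arrays centred on their medians and as deposited (adjusted p = 0.047 in both). With fry the FGF, retinoic acid and BMP lists passed upward (adjusted p = 0.0057 in each), and the WNT list did not (adjusted p = 0.17).

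The list of surface and nasal epithelium had 5 rises, 0 falls and 21 members that did not pass among 26 (8 and 0 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.27 with an estimated correlation). PKP2, a protein of desmosomes, rose 2.55-fold (1.35 ± 0.13, adjusted p = 3.7e-06), and KRT14, a keratin of basal epithelial cells, rose 2.51-fold (1.33 ± 0.17, adjusted p = 9.2e-05). That list did not pass without HH16 replicate 1 (adjusted p = 0.082) or without HH20 replicate 3 (adjusted p = 0.078). It did not pass with array weights, without HH16 replicate 1 and HH18 replicate 2 together or without probe sets designed against several transcripts either (adjusted p = 0.056, 0.086 and 0.12). Of 26 tested placodal transcription factor genes, 4 rose, 2 fell and 20 did not pass (5 and 3 adjusted over the list alone, camera adjusted p = 0.8), and the list's median (-0.06) and mean (0.07) differed in sign. Besides GATA3, its rises included PITX1 (0.88 ± 0.15) and IRX2 (0.72 ± 0.16), the latter well above background on 2 of the 3 HH16 arrays. Its fall of largest size was that of PNOC (-1.26 ± 0.15), which encodes the precursor of the peptide nociceptin and is no transcription factor. Of 44 axon guidance and adhesion genes 11 rose, 5 fell and 28 did not pass (14 and 6 adjusted over the list alone, camera adjusted p = 0.085, fry adjusted p = 0.0057). The semaphorins SEMA3D (1.35 ± 0.15) and SEMA5A (1.27 ± 0.16), the receptor EPHA5 (0.75 ± 0.13) and N-cadherin (CDH2, 0.83 ± 0.13) rose.

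Lists of other cell types held called genes over the same interval as the neuronal list. Of 29 mesenchymal genes 7 rose, 3 fell and 19 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.26). The matrix genes OGN (1.44 ± 0.18) and COL5A2 (1.43 ± 0.22) rose and the transcription factor SNAI2 fell (-1.02 ± 0.13). OGN was well above background on 1 of the 3 HH16 arrays. In the blood vessel list 2 of 21 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.085), with EGFL7, a protein secreted by endothelium, at 1.34 ± 0.21. In the erythrocyte list 1 of 11 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.098). In the macrophage and leukocyte list 2 of 17 rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.075), with CD74, a chaperone of class II histocompatibility proteins, at 0.66 ± 0.12. In the neural crest and glia list 1 of 15 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.35), and 10 of the 15 were lower by sign. The riser was the endothelin receptor EDNRB at 0.88 ± 0.13. Besides SNAI2, the falls were those of SOX8, from a mean log2 level of 7.20 to 6.67, and FABP7, from 10.99 to 10.66. In the lens list 1 of 15 rose and 1 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.23), and the riser was PROX1 (1.17 ± 0.12), a transcription factor also used outside the lens. In the eye and forebrain list 2 of 14 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.87), and its median (-0.06) and mean (0.03) differed in sign. Lists of other cell types passed upward in some settings. The blood vessel list passed without HH16 replicate 2 (adjusted p = 0.046), without HH16 replicate 3 (adjusted p = 0.029), with trimmed-mean scaling (adjusted p = 0.049), with arrays centred on their medians (adjusted p = 0.01) and as deposited (adjusted p = 0.00024). The macrophage and leukocyte list passed without HH16 replicate 2 (adjusted p = 0.046), with the replicate block (adjusted p = 0.046) and with trimmed-mean scaling (adjusted p = 0.049). It also passed with the mean of a gene's probe sets (adjusted p = 0.031), with arrays centred on their medians (adjusted p = 0.017) and as deposited (adjusted p = 1e-04). The erythrocyte list passed in a fit to the 6 arrays alone (adjusted p = 0.044) and as deposited (adjusted p = 0.033). None of these lists passed with an estimated correlation (adjusted p = 0.46 and 0.51).

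Of 45 cell cycle genes 2 rose, 5 fell and 38 did not pass (5 and 9 adjusted over the list alone, camera adjusted p = 0.23). Of 59 ribosomal protein genes 1 rose and 3 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.51), and RPS28 and RPL35A were among those that fell (-0.48 ± 0.10 and -0.37 ± 0.08). Of 31 hypoxia and glycolysis genes 5 rose and 0 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.19), including PDK4, a kinase that restrains pyruvate oxidation (1.29 ± 0.14), and NDRG1 (1.23 ± 0.22). Of 20 immediate early and stress genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.21), with the transcription factor KLF6 at 0.76 ± 0.09. Of 24 apoptosis genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.78), with the death receptor FAS at 1.17 ± 0.16.

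Over all probe sets, 2673 of 24489 changed between HH16 and HH20, 1423 higher and 1250 lower, and 240 of them changed at least 2-fold (164 higher, 76 lower). On the values as deposited, without normalization between arrays, 176 probe sets were called, 64.2% of them higher against 53.2%, and 47 of the 197 calls of named genes in the 3 comparisons were kept. Of the 101 such calls between HH16 and HH20, 76 were kept with each array left out. The count of probe sets was 1417 without HH20 replicate 1, 1612 without HH20 replicate 2 and 1766 without probe sets designed against several transcripts.

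The comparison of HH18 with HH16 covers the earlier step. STOM rose 3.03-fold, from a log2 level of 6.54 ± 0.10 (SD, n = 3) to 8.14 ± 0.04 (adjusted p = 3.7e-06), and PDK4 rose 2.85-fold (log2 change 1.51 ± 0.14, SE, adjusted p = 2.2e-05). The other rises named by the fixed rule were those of the secreted protein FAM19A1 (2.51-fold), the LIM protein FHL2 (2.47-fold), the synaptic vesicle protein SV2C (2.34-fold), DRD5 (2.32-fold), the hyaluronan receptor CD44 (2.27-fold) and the phosphodiesterase PDE4D (2.24-fold). FAM19A1 was well above background on 2 of the 3 HH16 arrays. SNTN was 3.25-fold lower at HH18 (-1.70 ± 0.18, adjusted p = 7.1e-05) and IGSF21 was 3.14-fold lower (-1.65 ± 0.24, adjusted p = 0.00061). They were followed by CLEC19A (2.61-fold lower), HAPLN1 (2.48-fold), the tubulin cofactor TBCC (2.42-fold), the uroplakin UPK1B (2.37-fold), TNFSF13B (2.36-fold) and GAL (2.32-fold).

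In the neuronal differentiation list 7 of 39 rose, 1 fell and 31 did not pass (11 and 2 adjusted over the list alone), with camera adjusted p = 0.0015 and adjusted p = 0.75 with an estimated correlation. The list's median log2 change was 0.22, and -0.04 as deposited, where the median of all tested probe sets was -0.25. By camera it still passed upward against other genes as deposited (adjusted p = 0.0017) and with arrays centred on their medians (adjusted p = 0.00027). ELAVL2 rose 2.24-fold (1.16 ± 0.14, adjusted p = 0.00014), CHGA rose 1.76-fold (0.81 ± 0.15, adjusted p = 0.0061) and the motor protein gene KIF5C rose 1.60-fold (0.68 ± 0.11, adjusted p = 0.0028). PCP4 fell (-1.12 ± 0.15, adjusted p = 0.00041) and was well above background on 1 of the 3 HH18 arrays. In the Notch and proneural list 2 of 24 rose, 1 fell and 21 did not pass (10 and 3 adjusted over the list alone), with camera adjusted p = 0.028 and adjusted p = 0.75 with an estimated correlation. Its median was 0.26, and -0.08 as deposited. By camera it still passed upward as deposited (adjusted p = 0.0029) and with arrays centred on their medians (adjusted p = 0.0053). It did not pass without HH16 replicate 1 (adjusted p = 0.1) or without HH18 replicate 3 (adjusted p = 0.38). It was also lost with array weights, with 3 other filters on dim probe sets, without HH16 replicate 1 and HH18 replicate 2 together and without probe sets designed against several transcripts (adjusted p = 0.061 to 0.16). Fry called neither the neuronal differentiation list (adjusted p = 0.16) nor the Notch and proneural list (adjusted p = 0.24). LHX2 rose in this step (0.76 ± 0.15, adjusted p = 0.0071), as did ALDH1A3 (0.72 ± 0.09), SEMA5A (0.94 ± 0.16), EPHA5 (0.75 ± 0.13), PKP2 (1.02 ± 0.13), EDNRB (0.65 ± 0.13), PROX1 (1.02 ± 0.12), NDRG1 (1.16 ± 0.22) and FAS (0.78 ± 0.16). The falls included WNT2B (-0.99 ± 0.12), the chemokine CXCL12 (-0.71 ± 0.10), SNAI2 (-0.81 ± 0.13) and the protease ST14 (-0.69 ± 0.13). In the BMP list 0 of 26 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.51). Those that fell were the ligands BMP4 (-0.88, adjusted p = 0.0085), which lost the call without HH18 replicate 2, and BMP2 (-0.57, adjusted p = 0.029). Of all 68 calls of named genes in this step, 35 were kept with each array left out.

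Markers of other cell types rose in the same step as these neuronal genes. Of 29 mesenchymal genes 3 rose and 1 fell (6 and 1 adjusted over the list alone), of 21 blood vessel genes 1 rose and 0 fell (1 and 0), and of 17 macrophage and leukocyte genes 1 rose and 0 fell (2 and 0). The macrophage growth factor receptor CSF1R rose (0.83 ± 0.18, adjusted p = 0.014), and lost the call without HH16 replicate 3, HH18 replicate 1 or HH18 replicate 2 (adjusted p = 0.064, 0.055 and 0.07). EGFL7 rose (0.83 ± 0.21, adjusted p = 0.029), and lost it without HH16 replicate 1 or HH18 replicate 2 (adjusted p = 0.07 and 0.12). The collagen COL6A1 rose (0.69 ± 0.15, adjusted p = 0.013), and lost it without HH16 replicate 3 or HH18 replicate 2 (adjusted p = 0.05 and 0.071). COL1A2 rose (0.67 ± 0.17, adjusted p = 0.03), and lost it without HH16 replicates 1 or 3 or HH18 replicates 1 or 2 (adjusted p = 0.071 to 0.1). COL6A3 rose (0.75 ± 0.21, adjusted p = 0.049), and lost it without each array but HH18 replicate 3 (adjusted p = 0.09 to 0.18). The macrophage and leukocyte list had camera adjusted p = 0.11 and passed upward without HH18 replicate 3 (adjusted p = 0.0038), with array weights (adjusted p = 0.043), with the replicate block (adjusted p = 0.047), with trimmed-mean scaling (adjusted p = 0.021), with arrays centred on their medians (adjusted p = 0.00027) and as deposited (adjusted p = 3.5e-07). The blood vessel list had camera adjusted p = 0.28 and passed upward without HH18 replicate 3 (adjusted p = 0.0065), with arrays centred on their medians (adjusted p = 0.00027) and as deposited (adjusted p = 0.00015). The erythrocyte list, with 0 of 11 called, had camera adjusted p = 0.47, and adjusted p = 0.0035 without HH18 replicate 3. The lens list, in which 1 of 15 rose and 1 fell (2 and 1 adjusted over the list alone), had camera adjusted p = 0.67, and adjusted p = 0.04, upward, with arrays centred on their medians. None of these 4 lists passed with an estimated correlation (adjusted p = 0.75).

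In the immediate early and stress list 4 of 20 rose and 1 fell in this step (5 and 2 adjusted over the list alone, camera adjusted p = 0.39), with KLF6 at 0.61 ± 0.09 (adjusted p = 0.001). The other rises were those of EGR1, DUSP1 and JUN, whose means were highest at HH18. Their mean log2 levels at HH16, HH18 and HH20 were 6.16, 6.99 and 6.42 for EGR1, 5.64, 6.21 and 5.85 for DUSP1, and 9.06, 9.62 and 9.22 for JUN. The difference between the steps did not pass for these genes (adjusted p = 0.11, 0.18 and 0.12 by limma). With all arrays, quantile normalization and none of the alternatives applied, no other list passed (camera adjusted p of 0.11 or above). The list of the olfactory receptor neuron lineage (camera adjusted p = 0.38) passed upward with arrays centred on their medians (adjusted p = 0.032). The cell cycle list (camera adjusted p = 0.55) passed downward with that centring (adjusted p = 0.0053) and as deposited (adjusted p = 0.03). The retinoic acid list (median -0.04, mean 0.07) and the apoptosis list (median -0.01, mean 0.02) differed in sign between median and mean. The signal ratio of the 3' to the 5' probe sets for actin, a sign of RNA quality, was higher at HH18 than at HH16, at a log2 ratio of 1.93 ± 0.17 (SD, n = 3) against 1.66 ± 0.11. It was 1.69 ± 0.16 at HH20. The same ratio for EF1A was 0.727 ± 0.23 at HH16, 0.639 ± 0.11 at HH18 and 0.616 ± 0.077 at HH20, and that for GAPDH was -0.16 ± 0.11, -0.0403 ± 0.022 and -0.139 ± 0.15, highest at HH18 like that of actin.

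Between HH16 and HH18, 1111 probe sets changed, 566 higher and 545 lower, and 82 changed at least 2-fold (48 higher, 34 lower). The higher share was 50.9%, against 29.2% with arrays centred on their medians and 4.55% as deposited, where 44 probe sets were called. The count was 403 without HH18 replicate 2, 399 without that array and HH16 replicate 1, 541 without HH16 replicate 2 and 634 without HH16 replicate 3. It was 641 without the filter on dim probe sets, 646 without a trend in the variance prior and 577 in a fit to the 6 arrays alone.

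In the later step, from HH18 to HH20, SST1 rose 4.0-fold (log2 change 2.0 ± 0.23, SE, n = 3 per stage, adjusted p = 0.00072). PLA2G10L, well above background on 1 of the 3 HH18 arrays, went from a log2 level of 4.34 ± 0.27 (SD) to 6.04 ± 0.50 (adjusted p = 0.00093). GATA3 rose 3.02-fold (1.60 ± 0.17), FGF3 2.48-fold (1.31 ± 0.16), KRT14 2.33-fold (1.22 ± 0.17), the annexin gene ANXA8L1 2.15-fold (1.10 ± 0.12) and MEGF10 2.09-fold (1.06 ± 0.14). TNFSF13B was 2.31-fold lower (-1.21 ± 0.14, adjusted p = 0.00072). SH3BGR was 1.98-fold lower (-0.99 ± 0.14, adjusted p = 0.002). These 9 of the 16 changes that the fixed rule names for this step remained past the threshold with each array left out. The other 7 did not. ASNS, which makes asparagine, rose 2.37-fold (1.24 ± 0.20) and lost the call without HH18 replicate 2 or any HH20 array (adjusted p = 0.052 to 0.072). HAPLN1 (-0.77 ± 0.12) lost it without HH20 replicate 2 (adjusted p = 0.068) or HH20 replicate 3 (adjusted p = 0.072). The falls of ADAM33 (-0.73), NID2 (-0.69) and STRIP2 (-0.69) were lost without each array but HH18 replicate 3 (adjusted p = 0.069 to 0.23). That of IGDCC3 (-0.63) was lost without each array but HH18 replicate 1 (adjusted p = 0.054 to 0.14), and that of PAMR1 (-0.62) without each of the 6 (adjusted p = 0.064 to 0.18). Of all 28 calls of named genes in this step, 11 were kept with each array left out.

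Of 26 tested members of the BMP list, 3 rose, 0 fell and 23 did not pass (6 and 0 adjusted over the list alone), with camera adjusted p = 2.7e-05, and adjusted p = 0.043 with an estimated correlation. BAMBI rose 2.08-fold (1.06 ± 0.13, adjusted p = 0.00091) and ID2 rose 1.42-fold (0.51 ± 0.07, adjusted p = 0.0036). BAMBI, ID2 and ID4, the members that rose, are targets or inhibitors of BMP signalling. The ligands BMP4 and BMP2, which fell from HH16 to HH18, were not called in this later step. Their mean log2 levels were 7.12 and 7.70 at HH16, 6.24 and 7.13 at HH18, and 6.36 and 7.26 at HH20. ID4 (0.69 ± 0.11, adjusted p = 0.0073) did not pass without HH20 replicate 1 (adjusted p = 0.072) or HH20 replicate 3 (adjusted p = 0.065). In the neuronal differentiation list 3 of 39 rose, 0 fell and 36 did not pass (6 and 0 adjusted over the list alone), with a median of 0.24, camera adjusted p = 1.4e-09 and adjusted p = 0.086 with an estimated correlation. The members that rose were ISL1, STMN2 and CHGA. STMN2 (0.73 ± 0.12, adjusted p = 0.0095) lost its call without HH18 replicate 1 (adjusted p = 0.051), HH20 replicate 1 (adjusted p = 0.094) or HH20 replicate 3 (adjusted p = 0.079). CHGA (0.75 ± 0.15, adjusted p = 0.043) lost it without each of the 6 arrays (adjusted p = 0.054 to 0.21).

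The retinoic acid list shifted upward with 0 of 16 members called (3 rose and 2 fell adjusted over the list alone, median 0.18, camera adjusted p = 0.0061, adjusted p = 0.18 with an estimated correlation). The list of surface and nasal epithelium had 1 rise, that of KRT14, and 0 falls among 26 (2 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.0035, adjusted p = 0.16 with an estimated correlation). In the WNT list WNT4 and NOTUM, an enzyme that inactivates WNT proteins, rose and 0 of 31 fell (4 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.031, adjusted p = 0.2 with an estimated correlation). That list did not pass without HH18 replicate 1 (adjusted p = 0.068), without HH20 replicate 3 (adjusted p = 0.16) or with arrays centred on their medians (adjusted p = 0.066). It was also lost with array weights, with fry, without the filter, with the mean of a gene's probe sets and without probe sets designed against several transcripts (adjusted p = 0.051 to 0.083). WNT4 (0.79 ± 0.16, adjusted p = 0.041) lost its call without each of the 6 arrays (adjusted p = 0.054 to 0.24). NOTUM (0.69 ± 0.13, adjusted p = 0.024) lost it without each array but HH18 replicate 3 (adjusted p = 0.085 to 0.17). The GnRH-related list also passed, and the other 17 lists did not. Of these, the Notch and proneural, hypoxia and glycolysis, and cell cycle lists passed without HH18 replicate 3 (adjusted p = 0.0042, 0.012 and 0.048), the last of them downward. The Notch and proneural list also passed with array weights (adjusted p = 0.049) and as deposited (adjusted p = 0.024). The FGF list passed upward without HH20 replicate 1 (adjusted p = 0.038), with arrays centred on their medians (adjusted p = 0.0072), with trimmed-mean scaling (adjusted p = 0.023), as deposited (adjusted p = 0.017) and without probe sets designed against several transcripts (adjusted p = 0.012). The lens list (camera adjusted p = 0.24) passed upward without those probe sets (adjusted p = 0.043), and the axon guidance list with the filter at the 60th percentile (adjusted p = 0.045). The erythrocyte list (camera adjusted p = 0.27) passed upward without HH18 replicate 2 (adjusted p = 0.016), without that array and HH16 replicate 1 (adjusted p = 0.025), with arrays centred on their medians (adjusted p = 0.047) and as deposited (adjusted p = 0.017). The blood vessel list (camera adjusted p = 0.48) passed without those 2 arrays (adjusted p = 0.033). In the immediate early and stress list the median was 0.03 and the mean -0.02.

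Between HH18 and HH20, 88 probe sets changed, 62 higher and 26 lower, and 17 changed at least 2-fold (15 higher, 2 lower). The higher share was 70.5%, against 88% with arrays centred on their medians, 82.8% with trimmed-mean scaling and 100% as deposited, where 10 probe sets were called and the median of all tested probe sets was 0.22. The count was 55 and 41 without HH18 replicates 1 and 2, and 24, 34 and 23 without HH20 replicates 1, 2 and 3. It was 32 without the filter on dim probe sets, 43 without a trend in the variance prior and 142 with array weights.

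**Figure D4:**
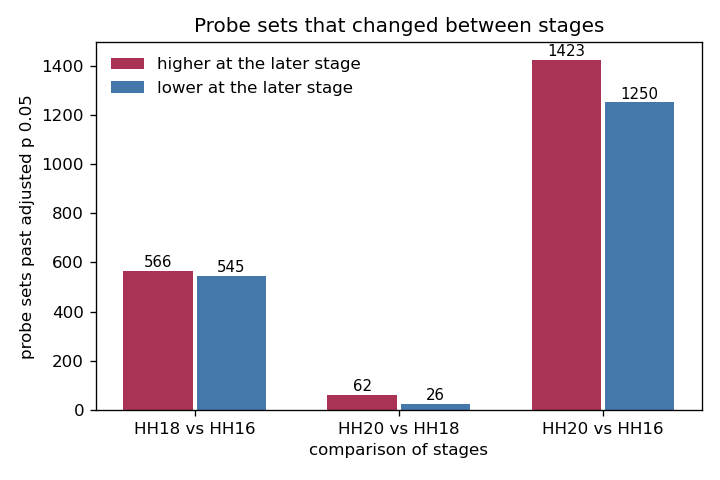
Number of probe sets past the adjusted p threshold of 0.05 (y axis) in each comparison of stages (x axis), with 1 bar for probe sets higher and 1 for probe sets lower at the later stage. The bars stand at 566 and 545 for HH18 against HH16, 62 and 26 for HH20 against HH18, and 1423 and 1250 for HH20 against HH16, and as deposited the 3 comparisons had 44, 10 and 176 calls.

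GNRH1, which encodes GnRH itself, had a log2 level of 8.80 ± 0.15 (SD, n = 3) at HH16, 8.63 ± 0.27 at HH18 and 8.63 ± 0.29 at HH20. It did not pass in any comparison, with a log2 change of -0.17 ± 0.15 (SE) between HH16 and HH20 (adjusted p = 0.55). Of the GnRH neuron and Kallmann-related list, 5 of 23 tested members rose between HH16 and HH20, 1 fell and 17 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.085). That list passed without HH16 replicate 2 (adjusted p = 0.046), with the mean of a gene's probe sets (adjusted p = 0.031), and with arrays centred on their medians and as deposited (adjusted p = 0.047 in both). It passed with fry as well (adjusted p = 0.023). EBF2 was among those that rose, and CXCL12, a guidance cue for migrating GnRH neurons, fell (-0.74 ± 0.10, adjusted p = 8.8e-05). From HH16 to HH18 1 member rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.72). From HH18 to HH20 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.026, adjusted p = 0.2 with an estimated correlation). It did not pass without HH18 replicate 1 (adjusted p = 0.071), HH18 replicate 3 (adjusted p = 0.09), HH20 replicate 2 (adjusted p = 0.14) or the filter on dim probe sets (adjusted p = 0.074). Fry did not call it either (adjusted p = 0.055).

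Those 2 members were ISL1 and FGF8. ISL1, a LIM homeodomain factor of differentiating neurons, rose from HH18 to HH20 (1.02 ± 0.18, adjusted p = 0.019), and lost the call without HH18 replicate 3, HH20 replicate 1 or HH20 replicate 3 (adjusted p = 0.057, 0.097 and 0.14). Its rise from HH16 to HH20 (0.79 ± 0.18, adjusted p = 0.0099) was lost without HH20 replicate 3 (adjusted p = 0.063). FGF8, a growth factor needed for GnRH neurons to form, lay at the threshold in the later step (0.83 ± 0.17, adjusted p = 0.05). It lost the call with each of the 6 arrays left out (adjusted p = 0.076 to 0.26). Its change from HH16 to HH20 was 0.52 ± 0.17 (adjusted p = 0.068, and 0.034 without HH16 replicate 1).

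TUBB3, a neuronal tubulin, rose from 9.02 ± 0.28 (SD, n = 3) at HH16 to 9.76 ± 0.11 at HH20 (0.74 ± 0.12, SE, adjusted p = 0.00054). Its rise from HH16 to HH18 (0.43 ± 0.12, adjusted p = 0.046) was 0.00 as deposited and was lost without HH16 replicate 1, HH16 replicate 3, HH18 replicate 1 or HH18 replicate 2 (adjusted p = 0.13, 0.064, 0.11 and 0.14). ELAVL4, an RNA-binding protein of neurons, rose by 1.04 ± 0.12 from HH16 to HH20 (adjusted p = 2.7e-05), and its rise from HH16 to HH18 (0.60 ± 0.12, adjusted p = 0.01) was lost without HH18 replicate 2 (adjusted p = 0.055). NEUROD1, a proneural factor, rose by 0.60 ± 0.15 from HH16 to HH20 (adjusted p = 0.017), and lost the call without HH16 replicate 1, HH16 replicate 3, HH20 replicate 1 or HH20 replicate 2 (adjusted p = 0.058, 0.063, 0.095 and 0.067). NEUROG1 did not pass in either step (adjusted p = 0.054 and 0.14).

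Of the factors that mark the placode or the early olfactory epithelium, PAX6 had log2 levels of 9.38 ± 0.04, 9.27 ± 0.13 and 9.14 ± 0.13 at HH16, HH18 and HH20 (SD, n = 3). DLX5 had levels of 10.74 ± 0.15, 10.65 ± 0.12 and 10.65 ± 0.01, and SOX2 had levels of 5.11 ± 0.16, 4.84 ± 0.27 and 4.84 ± 0.14, and was well above background on 2 of the 3 HH18 arrays. None of these 3 genes passed in any comparison. SOX10, a factor of neural crest and of olfactory ensheathing glia, had levels of 5.40 ± 0.25, 5.75 ± 0.40 and 5.45 ± 0.16 and did not pass either. ANOS1, a gene of Kallmann syndrome, was not well above background on any array.

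Across the 3 stages the F test called 2130 probe sets, and 152 as deposited. The count was 1244, 1238, 1224 and 1334 without HH16 replicate 2, HH16 replicate 3, HH20 replicate 1 and HH20 replicate 2. The 2 steps differed from each other for 8 probe sets, against 2408 with an unadjusted p under 0.05. The log2 change of the later step minus that of the earlier step was above 0 for 3 of them and below 0 for 5. Among them were the probe sets that represent PDK4 and STOM. The others with a symbol were dimmer probe sets of SRI, a calcium-binding protein, of the RNA-binding protein RBM10 and of NOTUM. The brightest probe sets of SRI and RBM10 were not among the 8, and the probe set that represents NOTUM elsewhere did not pass (1.18 ± 0.22, adjusted p = 0.077). The test of this difference called 0 by limma as deposited, without the filter or without a trend in the variance prior, 24 with arrays centred on their medians and 15 with trimmed-mean scaling. The count was 17, 20 and 33 without HH16 replicate 1, HH16 replicate 3 and HH18 replicate 3, 5 without HH20 replicate 1, and 0 without HH18 replicate 2, HH20 replicate 2 or HH20 replicate 3.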

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

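The fits with trimmed-mean scaling and without both HH16 replicate 1 and HH18 replicate 2, the use of the planned fits without either of these arrays as tests of explanations, and the test of the eye and forebrain genes were chosen only after the result was seen, and the readings of the eye and forebrain test and of the RNA quality test as undecided were also set after their values were seen. The gap between a single array and the others of its stage was not tested, since stages held 3 arrays.

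The later step differed from the earlier one for 8 probe sets by the test of that difference. PDK4 had mean log2 levels of 5.76, 7.27 and 7.05 at HH16, HH18 and HH20, a difference between steps of -1.73 (adjusted p = 0.024). STOM had levels of 6.54, 8.14 and 8.37, a difference of -1.37 (adjusted p = 0.024). A probe set of SRI, not the brightest of its gene, was higher at HH18 (6.26) than at HH16 (5.02) and HH20 (5.29), a difference of -2.21 (adjusted p = 0.035). A probe set of NOTUM, dimmer than the one that represents the gene elsewhere, had levels of 6.40, 5.56 and 6.65, a difference of 1.93 (adjusted p = 0.043), while the representing one did not pass (1.18, adjusted p = 0.077). A probe set of RBM10, likewise not the brightest of its gene, had levels of 8.30, 6.99 and 7.24, a difference of 1.56 (adjusted p = 0.043). Of 3 probe sets without a symbol, 1 had levels of 7.53, 5.89 and 5.88 (difference 1.62), another 8.90, 9.40 and 8.60 (difference -1.30) and the other 4.38, 6.08 and 6.07 (difference -1.73), each with adjusted p = 0.024. The last of them was not well above background on any HH16 array, so that its rise from HH16 has only a lower bound. Of 100 splits of the 9 arrays, the real one included, 4 gave as many such probe sets as the real 8. The highest other split gave 2088, which points to a structure of the samples, such as the separation of the stages, so this count of splits says little about the 8 themselves.

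Outside the main measurement, 1 of the 689 virus probe sets, which were left out of all tests, had a signal of 356.4 to 1001.2 over the 9 arrays, against 99th percentiles of the virus probe sets of 6.17 to 13.9.

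The earlier step held 1111 calls and the later one 88, a ratio of 12.6 that moved to 4.40 as deposited, 4.99 without HH16 replicate 1 and HH18 replicate 2, 5.34 in fits to the 6 arrays compared, 6.12 with array weights, 7.33, 6.94 and 7.29 without HH16 replicates 1, 2 and 3, 20.0 without the filter, and 34.0, 25.2 and 38.1 without HH20 replicates 1, 2 and 3. Changes of equal size lying on either side of the threshold are argued against by the mean squared change beyond noise, which was 2.52 times as large in the earlier step (2.01 to 3.20 with each array left out). High background in HH18 replicate 2 as the whole cause is argued against by a ratio of 9.83 without that array, which left 403 and 41 calls. Brightness of HH16 replicate 1 alone as the whole cause is argued against by a ratio of 7.33 without it. With trimmed-mean scaling the ratio was 11.3. All lay above the bound of 1.5, set for these tests after the result was seen. Trimmed-mean scaling applies 1 factor per array, so it cannot test brightness that acts differently on dim and bright probe sets, and this stays open. What also stays open is a processing batch that differed between stages, which the labels do not give and which cannot be told apart from stage. The samples are described here by stage and not by hours. Whether the 2 steps last equally long was not examined, so the ratio compares steps of stage and cannot show a rate of change. As a biological hypothesis, untested here, the placode may change more between HH16 and HH18.

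The neuronal differentiation list was higher at HH20 than at HH16, with a median log2 change of 0.45 over 39 genes. Eye or forebrain tissue taken along with older placodes could also bring neuronal transcripts: the 14 tested genes of that list had a median of -0.06 (bootstrap 95% interval -0.23 to 0.24), below the neuronal median, but 7 of them lay within 1 log2 unit of the floor and SIX6 (0.63) and OLIG2 (0.70) rose, so this stays open. With the mean 3' to 5' ratio of each array as a covariate the list had a camera p of 3.9e-12 and its mean change went from 0.46 to 0.48. That value met the bound set beforehand for RNA quality not being the cause, but the covariate moved a gene by a median of 0.018, too little for the test to decide. The ratios were close at HH16 and HH20: 1.66 ± 0.11 and 1.69 ± 0.16 (SD) for actin, 0.727 ± 0.23 and 0.616 ± 0.077 for EF1A, and -0.16 ± 0.11 and -0.139 ± 0.15 for GAPDH. They thus show no clear difference that could carry the list, but RNA quality that they do not capture stays open. Stage itself, the difference that the design names, was not tested against these 2 and stays open.

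Splits of the arrays into groups of the same sizes were counted for each result. For the F test across the 3 stages, 1 of 100 splits, the real one, gave as many as 2130 probe sets, and the highest other gave 1292, so that chance can be excluded at a share under 0.05. For 2 stages of 3 arrays, 10 splits are too few for a share under 0.05. There the real split and the highest other gave 1111 and 5 probe sets for HH18 against HH16, 88 and 0 for HH20 against HH18, and 2673 and 0 for HH20 against HH16, by limma, and 1 split of 10 reached the real count in each. For the number of shifted gene lists, the real split and the highest other gave 2 and 5, 6 and 9, and 3 and 4 in the same order, and 6, 2 and 4 of the 10 splits gave as many lists as the real one. In those splits the neuronal list had a camera p of 6e-11 for HH20 against HH18 (smallest other 4.1e-05), 4.3e-11 for HH20 against HH16 (smallest other 5.5e-07) and 6.6e-05 for HH18 against HH16 (smallest other 1.4e-05). Further called lists had a smaller camera p in another split than in the real one. They were Notch and proneural for HH18 against HH16 (0.0024, smallest other 3.2e-05) and GnRH-related for HH20 against HH18 (0.0057, smallest other 0.0011). The same held for surface and nasal epithelium for HH20 against HH16 (0.0036, smallest other 0.00068). For the remaining list calls the real split had the smallest p.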

How the results depend on the processing

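Trimmed-mean scaling, the filter at the virus percentile and the fit without HH16 replicate 1 and HH18 replicate 2 were chosen only after the result was seen. Signal over background limits the dim genes, and the cause was not tested for any change given here unless fewer probe sets or fewer arrays are named. Of 197 calls of named genes, 122 kept their direction and their side of the threshold with each array left out, 46 in every setting, and 111 in every setting but the values as deposited. Median centring kept 172, pseudocounts of 1 and 64 kept 186 and 194, no filter 155, no trend 145, array weights 190 and trimmed-mean scaling 173.

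As deposited, without normalization between arrays, 44 probe sets were called for HH18 against HH16, 10 for HH20 against HH18, 176 for HH20 against HH16, 152 by the F test and 0 by limma for a difference between the steps (2408 with an unadjusted p under 0.05 on normalized values). The shifted lists numbered 5 for HH18 against HH16 and 12 for HH20 against HH16. Of the 197 calls 47 were kept, 144 lost and 6 reversed. Those reversed were rises from HH16 to HH18, now TUBB3 0.00, HEY1 -0.13, SPRY2 -0.09, RDH10 -0.04, CENPF -0.07 and KIF11 -0.10, in values whose median over all probe sets was -0.25. From HH18 to HH20, where that median was 0.22, the uncalled changes of GNRH1, PAX6 and SOX2 were 0.34, 0.18 and 0.11.

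The steps differed for 24 probe sets with median centring, 15 with trimmed-mean scaling, 5 with the filter at the 60th percentile, 3 with array weights, and 0 by limma without the filter, without a trend or without HH16 replicate 1 and HH18 replicate 2. For HH18 against HH16 there were 641 calls and 1 list without the filter, where more probe sets were tested, 646 calls without a trend, 577 in a fit to the 6 arrays, and 399 calls and 1 list without those 2 arrays. For HH20 against HH18 there were 32 calls without the filter, 43 without a trend and 142 with array weights. For HH20 against HH16 there were 1766 calls without probe sets designed against several transcripts, where fewer were tested, and 7 lists with the mean of a gene's probe sets and 5 with trimmed-mean scaling. With an estimated correlation 0, 1 and 0 lists were called by camera for HH18 against HH16, HH20 against HH18 and HH20 against HH16. In the same order fry called 0, 4 and 9. With median centring the cell cycle list shifted downward for HH18 against HH16 and HH20 against HH16 (adjusted p = 0.0053 and 0.019) and the ribosomal list for HH20 against HH18 and HH20 against HH16 (adjusted p = 9.4e-05 and 0.0071), the former also with trimmed-mean scaling (adjusted p = 3.1e-08). With median centring the lists of the FGF, retinoic acid and BMP pathways, axon guidance, the olfactory receptor neuron lineage and GnRH-related genes shifted upward for HH20 against HH16 (adjusted p = 0.024 to 0.047). As deposited the cell cycle and ribosomal lists shifted downward (adjusted p = 0.048 and 0.011) and the olfactory receptor neuron lineage upward (adjusted p = 0.047, and 0.048 with the mean of a gene's probe sets) for HH20 against HH16.

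Changes of uncalled genes near 0 turned sign. From HH18 to HH20, GNRH1 was 0.10 with median centring and 0.02 with trimmed-mean scaling. DLX5 was 0.00 with median centring, -0.02 with array weights, -0.17 with the mean of its probe sets, -0.09 with trimmed-mean scaling and -0.03 without the 2 arrays, and SOX2 was 0.02 with a pseudocount of 1. With each array left out GNRH1 ranged from -0.14 to 0.16, DLX5 from -0.03 to 0.08 and SOX2 from -0.13 to 0.14. DLX5 was 0.05 from HH16 to HH18 with the mean of its probe sets. From HH16 to HH20 SOX10 was -0.08 without the 2 arrays and ranged from -0.08 to 0.17 with each array left out. The called rise of RPL10A from HH16 to HH20 (0.21) became -0.06 with the mean of its probe sets, one of which was called the opposite way.

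With each array left out in turn, the calls ranged from 403 (without HH18 replicate 2) to 1003 for HH18 against HH16, with 541 without HH16 replicate 2 and 634 without HH16 replicate 3. They ranged from 23 (without HH20 replicate 3) to 82 for HH20 against HH18, with 24, 34, 41 and 55 without HH20 replicate 1, HH20 replicate 2, HH18 replicate 2 and HH18 replicate 1, and from 1417 (without HH20 replicate 1) to 2497 for HH20 against HH16, with 1612 without HH20 replicate 2. The F test called 1224 (without HH20 replicate 1) to 2671, with 1238, 1244 and 1334 without HH16 replicate 3, HH16 replicate 2 and HH20 replicate 2. The steps differed for 0 by limma (without HH18 replicate 2, HH20 replicate 2 or HH20 replicate 3) to 33 (without HH18 replicate 3), with 17, 20 and 5 without HH16 replicate 1, HH16 replicate 3 and HH20 replicate 1. Shifted lists numbered 1 (without HH16 replicate 1) to 4 (without HH18 replicate 3) for HH18 against HH16, 4 (without HH18 replicate 1) to 8 for HH20 against HH18, and 2 (without HH16 replicate 1 or HH20 replicate 3) to 8 (without HH16 replicate 2) for HH20 against HH16.

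The replicate numbers do not pair the arrays: the deviations of 9 same-numbered pairs correlated at -0.13 to 0.056, with 0 pairs over 0.1, and 3 arrays correlated best with an array of their own number. Pairs with different numbers correlated at -0.18 to 0.14, and whether such arrays share a factor across stages was not tested. With the replicate number as a block, 818, 74 and 2319 probe sets were called for HH18 against HH16, HH20 against HH18 and HH20 against HH16, of which 789, 70 and 2266 were shared with the fit without it, and 9 differed between steps, 1722 passed the F test and 3, 6 and 4 lists shifted.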

Other observations

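No test in this part was chosen only after its result was seen, but the reading of the test of peptide genes was changed after its value was seen, and the genes that prompted the lists were left out of them.

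A further list held genes of developmental timing, namely the LIN28 proteins, which block maturation of the let-7 microRNA, and targets of let-7. Of its 17 tested genes, 4 fell and 1 rose. LIN28B had a log2 change of -0.94 from HH16 to HH20 (adjusted p = 0.0034), and LIN28A was not well above background at HH20 and was at least 1.75-fold higher at HH16 (adjusted p = 0.0024). SALL4, a zinc finger factor of pluripotent cells, changed by -0.53 (adjusted p = 0.02) and the cell cycle factor E2F5 by -0.33 (adjusted p = 0.045), while the receptor TGFBR1 rose by 0.45 (adjusted p = 0.034). The other 12 did not pass.

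The falls of PRTG, NR6A1 and IGDCC3 between HH16 and HH20 raised the hypothesis that developmental timing genes may fall as a group. Without those 3 genes the list of 17 had a median log2 change of -0.08 and a mean of -0.19, with a camera p of 0.035 at the preset correlation and 0.073 with an estimated correlation, so that the test left the hypothesis open. No technical explanation was tested for it.

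GAL and PNOC were lower and SST1 was higher at HH20, which raised the hypothesis that genes of neuropeptides and peptide hormones may shift as a group. The other 16 tested genes of such a list had a median of 0.08 (camera p = 0.17, and 0.26 with an estimated correlation). The test asks for a shift in 1 direction, and its members were called both ways, so that the bound set for it beforehand, a p above 0.05, which this value met, cannot decide and the hypothesis stays open. Among them PENK, a precursor of opioid peptides, rose by 1.33 (adjusted p = 3.3e-05), CALCA by 0.96 (adjusted p = 0.011), and CCK, the precursor of cholecystokinin, changed by -0.67 (adjusted p = 0.02), and 13 did not pass.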
